A study of Mus musculus with 2 samples.

How the data were processed

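Total lung cells were profiled with the 10x Chromium 3' v3 droplet chemistry, which tags each captured transcript with a unique molecular identifier (UMI), per the labels' protocols. There were 2 libraries, each from 3 pooled mice aged 5 weeks, 1 per genotype: floxed Lkb1 without Cre (control) and with Nkx2.1-Cre (Cre). The deposited values are raw UMI counts per gene and barcode, not normalized, per the file headers and the values themselves, which are whole numbers. The tools named are Cell Ranger 3.1.0 and STAR, and the build is mm10, per the submitters' processing notes, while the matrix header names software version 3.0.0. The role of each tool, the gene annotation and the filters are not given in the sources used here. No barcode in either matrix held under 500 UMIs. Both matrices list 31053 genes, of which 30934 were matched by gene identifier to the GENCODE M21 annotation of GRCm38, the source of the coordinates; 71 symbols occur more than once.

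Cells were kept at 200 or more genes, 500 or more UMIs and at most 20% mitochondrial UMIs. In the control library 86 barcodes had under 200 genes and 638 exceeded the mitochondrial limit, against 1035 and 675 in the Cre library. Scrublet, as in scanpy 1.11.5 with an expected rate of 0.06, called 472 control (3.50%) and 434 Cre (2.75%) barcodes doublets, and 453 and 422 otherwise passing barcodes were removed for this. This left 12410 control cells with 68621154 UMIs and 14689 Cre cells with 74574232 UMIs, at medians of 1337.5 and 1329 genes. Free RNA was not subtracted. Xist stood at 838 CPM in the control and 978 CPM in the Cre library with Y-linked genes near 0 in both.

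Both libraries were clustered together without integration: scaling to 10000 UMIs and logarithm, 2000 variable genes ranked within each library, 30 principal components, 15 neighbours weighted by shared neighbours, and Leiden at resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9), which gave 51 clusters. Names ending in -like come only from markers of 42 classes fixed before the data were examined. Also fixed then were the gene lists, the rule for named genes, all but 4 of the alternatives and the statistics. The subtraction of the all-gene median from list medians, described below, was not among these. A cluster took the class with most markers among its top 10 genes by fold over the other cells, or the highest mean marker level where none was there. It stayed unnamed with a mean marker log2 level under 1.0, with fewer than 3 markers at 2-fold, with more markers of another class among its top genes, with a score of another lineage of at least 0.8 and 0.4 of its own, or with a low depth and no marker among its top genes. The values 1.0, 0.8 and 0.4 were set after seeing the data. Unnamed clusters held 3.76% of control and 5.33% of Cre cells, of which the clusters set aside for markers of 2 lineages made up 3.62% and 2.55% of all kept cells. Mesothelial-like cells count among the mesenchymal cells. The leading genes of some named clusters also differed between the libraries, such as Clca1 and Muc5b in the club-like, Il13 and Il5 in the ILC2-like and Ccl17 in the cDC2-like cluster, so their shares are descriptions.

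Shares carry Clopper-Pearson 95% intervals. Within each of 25 classes with at least 50 cells per library, UMIs were summed per library and expressed as CPM of that sum, and the fold of Cre over control carries the exact conditional 95% interval of a ratio of Poisson counts. A fold against 0 UMIs is a lower bound against a floor of 3 counts in the class sum. A gene could be named if it had at least 50 UMIs over both libraries, and, in the library where it was higher, at least 50 CPM and at least 0.5 of its CPM over the other kept cells. Genes were ranked by the bound of their interval nearest 1, and the 12 highest and 12 lowest in each epithelial class and the 5 highest and 5 lowest in the other classes were named. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor and predicted genes, and genes of the dissociation and sex-linked lists, were left out of this ranking. Members of the fixed lists may be named as examples. The rule's genes of the pDC-like, mesothelial-like, lymphatic-like and erythroid-like cells, and most of those of B cell-like and NK-like cells, are not printed, and the results of some other genes named by the rule or used in a test are not reported here.

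For 33 gene lists, the median over genes with at least 20 UMIs of log2((Cre CPM + 5)/(control CPM + 5)) was taken per class, and its percentile among 10000 random lists of the same size, matched in 20 bins of expression, describes these libraries only. Because the median of all genes differed from 0, by up to 0.39 in an epithelial class, list medians are given less that median. This subtraction, and the count of members against that median, were not among the statistics fixed in advance. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs. Where such a share was 0, the limit given is 3 cells of the total, which bounds cells with a UMI at that depth and not cells expressing the gene. With 1 library per genotype no test between genotypes was made. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.

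The intervals were tested on simulated Poisson counts with known folds. The intervals assume that model, and the simulation had no spread among cells, mice or libraries, so it checks the calculation only. In AT2-like cells, over 10962 genes, the interval held the true fold for 95.3% of unchanged genes, and lay wholly on the right side of 1 for 85.9% of genes changed 1.5-fold, 98.3% at 2-fold and 100% at 4-fold. In club-like cells, over 8487 genes, these values were 95.9%, 67.2%, 94.5% and 100%. Alternatives fixed in advance were a stricter cell filter (500 genes, 1000 UMIs, 10% mitochondrial), a filter on 200 genes alone, no doublet removal, Leiden resolutions 0.5 and 2.0, separate clustering of the libraries, naming each cell from its own markers, neighbours balanced between libraries, shares within the lineage, the mean over cells of CPM, median-ratio scaling, thinning to 1000 UMIs, pseudocounts of 1 and 20 CPM and minimums of 1 and 100 UMIs. Chosen after seeing the data were a denominator without erythroid-like cells, T cell-like cells without the cluster led by Rag1 and Dntt, the deeper alveolar fibroblast-like cluster alone and list members expressed in the class.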

Results

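Total lung cells of mice aged 5 weeks were profiled by droplet single-cell RNA sequencing in 2 genotypes. Control mice carried floxed alleles of Lkb1, a serine/threonine kinase that activates AMPK and related kinases and whose gene symbol is Stk11. The other mice carried the same alleles with an Nkx2.1-Cre driver. Nkx2-1 is a transcription factor of lung epithelial progenitors, so the driver directs recombination to that lineage. Cells of 3 mice were pooled into 1 library per genotype, called the control and the Cre library here. The control library held 13587 barcodes with 74219499 unique molecular identifiers (UMIs, each a captured transcript), and the Cre library held 16821 barcodes with 81598779 UMIs. After filtering, 12410 control cells with a median of 3607 UMIs and 14689 Cre cells with a median of 3253 UMIs were compared.

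The comparison asks how the cells of the lung, epithelial cells first, differed between these genotypes. With 1 pooled library per genotype there was no replicate spread and no test, and genotype cannot be separated from the mice, the pool or the library. Folds are ratios of CPM, a gene's share of the summed UMIs of its class and library. The values in parentheses after a fold or a share are exact 95% intervals that cover counting error only. A gene list is described by its median log2 ratio, Cre over control, less the median of all measured genes of the class. That all-gene median was 0.16 in AT2-like, 0.39 in club-like, 0.09 in AT1-like and 0.08 in ciliated-like cells. A list member was counted as higher or lower when it lay at least 1.5-fold from that all-gene median.

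Stk11, the targeted gene, was lower in both alveolar epithelial classes of the Cre library. It stood at 0.598 (0.528 to 0.677) times the control level in AT2-like cells, the surfactant-producing cells of the alveolus, with 49.8 CPM in the control and 29.8 CPM in the Cre library. In AT1-like cells, the flat cells of gas exchange, the ratio was 0.585 (0.350 to 0.994). Club-like cells, the secretory cells of the airway, had a ratio of 1.08 (0.823 to 1.42) and ciliated-like cells one of 0.851 (0.591 to 1.22). These ratios were not corrected for the shift of the other genes. Over genes with at least 50 UMIs the median ratio was 1.55 in club-like, 1.19 in AT2-like and 1.05 in AT1-like and in ciliated-like cells. Stk11 thus lay below the typical gene of club-like cells too. Outside the epithelium the ratio ranged from 0.856 in aerocyte-like to 1.66 in cDC2-like cells. Stk11 (ENSMUSG00000003068) lies on the plus strand of chromosome 10, from 80115803 to 80130682 (GRCm38). Tags come from the 3' ends of transcripts and may lie outside the deleted part, whose place the labels do not give, so these levels check little.

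AT1-like cells, group 2 innate lymphoid (ILC2-like) cells and cDC2-like dendritic cells made up larger shares of the Cre library, and neutrophil-like and capillary endothelial-like cells smaller ones. AT1-like cells were 0.999% (0.832 to 1.19) of control and 2.24% (2.01 to 2.49) of Cre cells, a log2 ratio of 1.16 (0.86 to 1.47). ILC2-like cells, lymphocytes that secrete IL-5 and IL-13, were 1.14% (0.957 to 1.34) of control and 2.87% (2.61 to 3.16) of Cre cells, a log2 ratio of 1.34 (1.06 to 1.62). Dendritic cells of the cDC2-like class, which present antigen to helper T cells, had a log2 ratio of 1.18 (0.87 to 1.496), or 0.63 with the libraries clustered separately. The leading genes of that cluster include Xcr1 and Ccl22, fixed markers of cDC1 and mature dendritic cells. No cluster took those names, so the class may hold other dendritic cells. Regulatory T (Treg-like) cells had a log2 ratio of 0.74 (0.49 to 0.99). Alveolar macrophage-like cells were 4.03% of control and 6.42% of Cre cells (log2 ratio 0.67, 0.51 to 0.83), and interstitial macrophage-like cells had a log2 ratio of 0.68 (0.44 to 0.92), or 1.15 when each cell was named from its own markers. Neutrophil-like cells were 15.6% (15.01 to 16.3) of control and 7.50% (7.07 to 7.93) of Cre cells, a log2 ratio of -1.06 (-1.17 to -0.95), at median depths of 2574 and 1520 UMIs. Aerocyte-like and general capillary-like endothelial cells, the 2 capillary types of the alveolus, had log2 ratios of -0.97 (-1.21 to -0.74) and -0.75 (-0.90 to -0.59). Within the endothelial lineage these were -0.31 (-0.54 to -0.07) and -0.080 (-0.24 to 0.074). AT2-like cells were 9.79% (9.27 to 10.3) of control and 11.2% (10.7 to 11.8) of Cre cells (log2 ratio 0.20, 0.09 to 0.31), and the sign turned when each cell was named from its own markers (-0.050) or when only epithelial cells were the denominator (-0.061).

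By lineage, epithelial cells were 13.3% of control and 15.9% of Cre cells (log2 ratio 0.26, 0.17 to 0.35), mesenchymal cells 12.3% of control and 15.3% of Cre cells (0.31, 0.22 to 0.41), endothelial cells 13.8% of control and 8.70% of Cre cells (-0.67, -0.77 to -0.56) and immune cells 56.3% of control and 51.95% of Cre cells (-0.12, -0.16 to -0.07). Club-like cells had a log2 ratio of 0.12 (-0.15 to 0.38), ciliated-like cells -0.46 (-0.90 to -0.01), or -0.96 with separate clustering, T cell-like cells -0.02 (-0.16 to 0.11), or -0.35 without the cluster led by Rag1 and Dntt, and smooth muscle-like cells -0.02 (-0.36 to 0.32). B cell-like cells had a log2 ratio of -0.42 (-0.52 to -0.32), or -0.91 with the stricter filter, NK-like cells 0.35 (0.15 to 0.56), classical monocyte-like cells -0.37 (-0.58 to -0.17) and nonclassical monocyte-like cells -0.29 (-0.49 to -0.10). Alveolar fibroblast-like cells were 7.20% of control and 9.84% of Cre cells (log2 ratio 0.45, 0.33 to 0.57), at median depths of 998.5 and 2225.5 UMIs, and their ratio turned to -0.094 with coarser clusters and was 0.97 with the stricter filter. Adventitial fibroblast-like cells had a log2 ratio of 0.42 (0.20 to 0.64), which turned to -0.12 when the libraries were clustered separately. Venous-like cells had a log2 ratio of -0.37 (-0.59 to -0.15), and plasma cell-like cells one of 1.19 (0.23 to 2.23); the former turned in 3 alternatives, to 0.73 with separate clustering, and the latter to -0.25 there. The log2 ratios of lymphatic-like, mesothelial-like and pDC-like cells were -0.28 (-0.64 to 0.09), -0.37 (-0.66 to -0.09) and 0.23 (-0.26 to 0.72), and within their lineages those of lymphatic-like and mesothelial-like cells were 0.39 and -0.69. Erythroid-like cells were 0.540% of control and 2.83% of Cre cells. Basophil or mast-like cells, 5 control and 37 Cre cells, had a log2 ratio of 2.64 (1.29 to 4.35). That ratio was 0.57 with the filter on 200 genes alone, 0.11 with each cell named from its own markers and 1.08 with balanced neighbours. Clusters left unnamed held 3.76% of control and 5.33% of Cre cells. One of them, cluster 23, led by Spp1, Ccl24, Mmp12 and Arg1, held 0 control and 382 Cre cells, and since it came from 1 library it may be that library rather than a cell type. The leading genes of the club-like and ILC2-like clusters include Clca1, Muc5b and Reg3g, and Il13 and Il5, which also differed between the libraries.

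**Figure D1:**
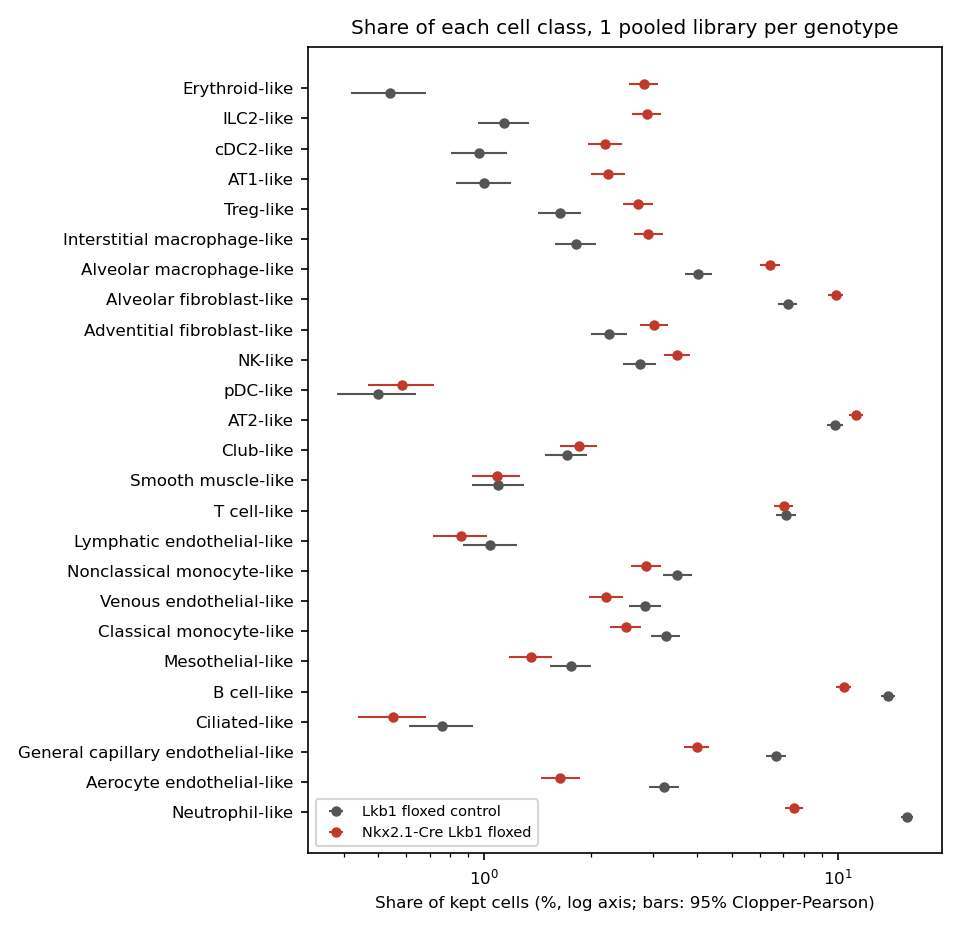
Share of kept cells in each of 25 classes (percent, log axis) in the control (grey) and Cre (red) library; points are shares and bars Clopper-Pearson 95% intervals, which cover counting error only. ILC2-like cells sit at 1.14% and 2.87%, AT1-like cells at 0.999% and 2.24%, and neutrophil-like cells at 15.6% and 7.50% of the control and Cre library.

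In AT2-like cells the Cre library held many UMIs of genes that were close to absent in the control. Sox9, a transcription factor of the distal tip progenitors of the embryonic lung, was 847-fold higher (289 to 4108), and Retnla, a secreted resistin-like protein induced by IL-4 and IL-13, was 278-fold higher (258 to 299.5), at 54.04 CPM in the control and 15012 CPM in the Cre library. Cxcl5, a chemokine that attracts neutrophils, was 404-fold higher (138 to 1959.8), and Rgs4, a regulator of G protein signalling, was 1093-fold higher (196 to 43194). Slc26a4, the anion exchanger pendrin, was 28.9-fold higher (24.1 to 34.9). Gclc, the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, was 5.77-fold higher (5.58 to 5.97) and Gpx2, a glutathione peroxidase, was 7.37-fold higher (6.23 to 8.77). Also among the 12 highest were the splicing regulator Rbm24 (344-fold, 117 to 1672), the cytoskeletal adaptor Sorbs2 (121-fold, 65.3 to 252), the amino acid transporter Slc38a4 (7.98-fold, 6.97 to 9.17) and Rgs10 (6.75-fold, 6.22 to 7.34). Sox9 (ENSMUSG00000000567) lies on the plus strand of chromosome 11 from 112782224 to 112787760, and Retnla (ENSMUSG00000061100) on the plus strand of chromosome 16 from 48842551 to 48844461; both are protein-coding.

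Several enzymes were among the 12 lowest genes in AT2-like cells. Cyp2b10, a cytochrome P450 enzyme, was 14.8-fold lower (11.3 to 19.7), Pon1, the lactonase paraoxonase 1, was 9.06-fold lower (7.20 to 11.5), Sord, sorbitol dehydrogenase, was 4.35-fold lower (3.78 to 5.02), and Ces1d, a carboxylesterase, was 3.78-fold lower (3.56 to 4.02). Spink5, a serine protease inhibitor, was 19.03-fold lower (13.7 to 27.1) and the stress-responsive gene Nupr1 was 10.4-fold lower (9.61 to 11.3). The muscle-type genes Cox6a2 and Myh7 were 10.1-fold lower (9.01 to 11.3) and 9.24-fold lower (7.70 to 11.2). Acoxl, an acyl-CoA oxidase-like gene, was 4.28-fold lower (3.98 to 4.60), Bex2 was 5.89-fold lower (5.38 to 6.45), Nrn1, or neuritin, was 5.53-fold lower (4.60 to 6.67) and the secretoglobin Scgb1c1 was 3.67-fold lower (3.26 to 4.13). These ratios rest on 13083611 control and 14380517 Cre UMIs. The class joined cluster 7, with 1195 control and 31 Cre cells, and cluster 2, with 20 control and 1621 Cre cells; Slc26a4, Gclc, Sox9, Il33 and Sftpd lead the latter and Acoxl, Bex2, Cox6a2 and Sftpc the former, so the class was compared as a whole.

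Among the lists fixed before the data were examined, genes induced by CREB and its CRTC coactivators and genes of neutrophil chemokines and NF-kB lay highest in AT2-like cells. The CRTC and CREB list had a relative median of 1.12, with 11 of 14 measured members higher and 0 lower, at percentile 100 among 10000 random lists matched on expression. Areg, an EGF receptor ligand, was 4.58-fold higher (4.32 to 4.87), Ppargc1a, a coactivator of mitochondrial biogenesis, was 4.47-fold higher (3.72 to 5.40), and the phosphodiesterase Pde10a was at least 104-fold higher. The chemokine and NF-kB list had a relative median of 1.10, with 11 of 18 members higher and 0 lower (percentile 100), but 0.63 with pseudocount 20 and 0.66 with cells named one by one; Lcn2, an iron-sequestering antibacterial protein, was 2.70-fold higher (2.64 to 2.76). Cell cycle genes had a relative median of 0.58 (7 of 16 higher), genes of the type 2 immune response 0.46 (5 of 12 higher) and genes of the transitional alveolar state 0.29 (6 of 17 higher, 1 lower). Il33, an alarmin that activates ILC2 cells, was 3.13-fold higher (3.01 to 3.26). The type 2 median before the all-gene median was taken off was 0.62, and 1.58 with each cell at 1000 UMIs. The immediate early genes that dissociation induces also lay higher, at 0.52 (9 of 20 higher), and Fosb stands on both that list and the CRTC and CREB list. Nr4a1 and Nr4a2, nuclear receptors induced by CREB, were 2.65-fold higher (2.47 to 2.84) and 5.51-fold higher (4.56 to 6.69). The chemokine Cxcl1 was 3.34-fold higher (2.80 to 4.001) and the keratin Krt8 1.84-fold higher (1.76 to 1.93). Mki67, a proliferation marker, was 5.11-fold higher (3.62 to 7.38).

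Surfactant and AT2 identity genes had a relative median of -0.51, with 8 of 20 members lower and 1 higher (percentile 0). Sftpc and Sftpb, the hydrophobic surfactant proteins, stood at 0.690 (0.689 to 0.691) and 0.686 (0.680 to 0.692) times the control level, Lyz2, a lysozyme, at 0.445 (0.442 to 0.447), Napsa, an aspartic protease that processes surfactant protein, at 0.594 (0.584 to 0.604) and Lpcat1, an enzyme of surfactant lipid synthesis, at 0.625 (0.611 to 0.639). Sftpd, a collectin, was 1.74-fold higher (1.72 to 1.75) and Nkx2-1 was 1.40-fold higher (1.34 to 1.47). Genes of the AMPK, SIK and LKB1 pathway had a relative median of 0.08, with 1 of 18 members higher and 1 lower. Fatty acid and sterol synthesis (-0.10), fatty acid oxidation (-0.09), glycolysis (0.03), oxidative stress (-0.02) and AT1 identity genes (0.08) lay near the all-gene median. MHC class II (0.34), MHC class I (0.29), unfolded protein response (0.27) and oxidative phosphorylation genes (0.27) lay above it, and club secretory genes (-0.39) below.

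With each cell thinned to 1000 UMIs, Retnla was found in 2.39% of control and 73.8% of Cre AT2-like cells, against 0.352% and 13.7% of B cell-like cells, where the source of its UMIs was not settled. Unthinned, the AT2-like shares were 12.5% and 91.3%. Sox9 was found in 0 of 1215 control cells, which allows a share of cells with a UMI of up to 0.247%, and in 13.9% (12.3 to 15.7) of 1646 Cre cells; unthinned, the shares were 0.247% and 49.1%. In B cell-like cells Sox9 was in 0% and 0.209%. Il33 was found in 19.8% and 46.8% of AT2-like cells (unthinned 75.9% and 91.2%), and in 0.117% and 0.487% of B cell-like cells. Cxcl5 was found in 0 of the control and 3.098% (2.32 to 4.05) of the Cre AT2-like cells (unthinned 0.165% and 6.48%), and in 0% and 0.0696% of B cell-like cells. Thinning left out 0 control and 6 Cre AT2-like cells, whose median depths were 10673 and 8203.5 UMIs, and 11 and 85 B cell-like cells, whose median depths were 3043 and 1988 UMIs. Free RNA was heavy in both libraries, since Sftpc was found in 44.4% of control and 48.9% of Cre B cell-like cells after thinning.

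In AT1-like cells, genes of AT1 identity lay lower and surfactant and CRTC and CREB genes higher in the Cre library. AT1 identity genes had a relative median of -0.40, with 6 of 16 members lower and 0 higher. Hopx, a homeodomain protein, stood at 0.577 (0.553 to 0.602) times the control level, Vegfa, an endothelial growth factor, at 0.513 (0.473 to 0.557) and Ager, the receptor RAGE, at 0.706 (0.684 to 0.729). The CRTC and CREB list had a relative median of 0.998 (9 of 11 higher), fatty acid and sterol synthesis 0.68, the unfolded protein response 0.42 and immediate early genes 0.45. The relative median of the fatty acid and sterol synthesis list was 0.063 over members expressed in the class and 0.30 with each cell at 1000 UMIs, and that of the CRTC and CREB list 0.64 with pseudocount 20 and 0.65 with cells named one by one. Aqp1, a water channel, was 12.7-fold higher (7.63 to 22.9), Kcne2, a potassium channel subunit, 13.8-fold higher (5.30 to 51.5), Trp53inp1, a gene induced by p53, 17.7-fold higher (3.04 to 715), and Clu, the secreted chaperone clusterin, 3.96-fold higher (2.68 to 6.05). Slc38a4 and Rbm24, with 0 control UMIs, were at least 9.17-fold higher and at least 7.85-fold higher than the floor of 3 counts. Wfdc1, Rassf2, Phlda1, Ramp1, Cldn3 and Ociad2 were the other genes among the 12 highest, between 4.09 and 9.41-fold higher. Cyp4b1, a cytochrome P450 enzyme, was 5.36-fold lower (4.38 to 6.57), Abca1, a cholesterol exporter, 3.95-fold lower (2.77 to 5.65), Igfbp6 3.79-fold lower (3.30 to 4.35) and Pdgfa, a growth factor for fibroblasts, 2.41-fold lower (2.08 to 2.79). Plagl1, Gpm6a, Ankrd1, S100a6, Pmp22, Fjx1, Tpm2 and Rnd1 were between 2.30 and 4.60-fold lower.

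Surfactant and AT2 identity genes had a relative median of 1.16 in AT1-like cells, with 14 of 19 members higher and 0 lower. Sftpc was 2.46-fold higher (2.35 to 2.58) and Slc34a2, a phosphate transporter of AT2 cells, 4.71-fold higher (3.02 to 7.73), and Etv5, a transcription factor of AT2 cells, 10.5-fold higher (1.74 to 429). The signs of Etv5 and Trp53inp1 turned with each cell at 1000 UMIs, and that of Slc34a2 in the mean over cells. A library with 0 UMIs after thinning was set at the floor of 3 counts, so the turns of Etv5 and Trp53inp1 may come from that floor. Sftpc reached 13426 CPM in AT1-like cells of the Cre library against 32353 CPM over the other cells, so free RNA from AT2 cells is not excluded as a part. Before the all-gene median was taken off, the list's median was 1.25, and it was 0.39 with each cell at 1000 UMIs and 0.32 over members expressed in the class. AT1-like cells were shallow, with median depths of 978.5 and 1022 UMIs.

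Club-like cells of the Cre library held many more UMIs of goblet and mucous genes and fewer of club secretory genes. Chil4, a chitinase-like protein of allergic airways, was 1034-fold higher (732.5 to 1512), Clca1, a secreted goblet cell protein, 74.7-fold higher (66.8 to 83.8), Muc5b, a gel-forming mucin, 10.03-fold higher (9.54 to 10.6) and Agr2, a disulfide isomerase needed for mucin folding, 10.2-fold higher (9.19 to 11.4). Tff1, a trefoil peptide of mucous cells, and Itln1, the lectin intelectin 1, had 0 control UMIs and were at least 185-fold higher and at least 178-fold higher than the floor of 3 counts. Fcgbp, a mucus protein, was 28.5-fold higher (20.8 to 40.2), Reg3g, an antibacterial lectin, 9.61-fold higher (9.36 to 9.86) and Retnla 11.5-fold higher (11.3 to 11.7). The thioesterase Them5 (147-fold, 62.5 to 454) and the ferlin Fer1l6 (30.005-fold, 17.96 to 54.1) were also among the 12 highest. Among the 12 lowest were the airway surface protein Bpifa1 (4.43-fold, 4.28 to 4.59), the oxidising enzymes Cyp4b1 (3.52-fold, 3.12 to 3.98) and Fmo2 (2.42-fold, 2.18 to 2.70), the sulfotransferase Sult1d1 (3.34-fold, 2.81 to 3.99), Pon1 (5.06-fold, 4.43 to 5.81) and Scnn1b, a subunit of the epithelial sodium channel (2.73-fold, 2.33 to 3.20). Chil4 (ENSMUSG00000063779) and Clca1 (ENSMUSG00000028255) lie on the minus strand of chromosome 3, from 106201490 to 106219507 and from 145003817 to 145032776. Rgcc, Sfta2, Scgb1c1, Slc16a11 and Sftpa1 were between 1.81 and 5.65-fold lower.

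The goblet and mucous list had a relative median of 1.97 in club-like cells, with 12 of 14 members higher and 1 lower (percentile 100), or 1.15 with pseudocount 20. Spdef and Foxa3, transcription factors of goblet cells, were 4.56-fold higher (2.69 to 8.13) and 3.63-fold higher (2.19 to 6.25), and Tff2, a trefoil peptide, 8.11-fold higher (7.77 to 8.46). Top2a, a topoisomerase of dividing cells, was 18.5-fold higher (7.61 to 58.6), a sign that turned with each cell at 1000 UMIs. Club secretory genes had a relative median of -0.74, with 8 of 14 members lower and 0 higher; Cyp2f2, a cytochrome P450 enzyme of club cells, stood at 0.764 (0.751 to 0.777) and Scgb1a1, the main club cell secretoglobin, at 0.687 (0.686 to 0.688) times the control level. Aldh1a1, a retinaldehyde dehydrogenase, and the secretoglobin Scgb3a1 stood at 1.75 (1.70 to 1.80) and 1.59 (1.57 to 1.60). Type 2 response (0.69), transitional state (0.61), CRTC and CREB (0.60, 8 of 15 higher), unfolded protein response (0.52), cell cycle (0.46) and immediate early genes (0.23) lay above the all-gene median, cilia genes near it (-0.07) and surfactant genes below (-0.77, 13 of 20 lower). When each cell was named from its own markers, with goblet markers as a class of their own, the goblet median before the all-gene median was taken off went from 2.36 to 0.19 and the relative median to -0.13, and the signs of Fcgbp, Foxa3, Reg3g, Scgb3a1 and Tff2 turned. The cells highest in goblet markers leave the club-like class under that naming, so it cannot test the goblet values there. Before the all-gene median was taken off, surfactant genes turned to 0.076 under that naming and cilia genes to -0.24 under median-ratio scaling. The relative median of the type 2 list was -0.0014 over genes with at least 1 UMI, 2.82 from 100 UMIs and 3.24 with each cell at 1000 UMIs. That of the CRTC and CREB list was 0.90 with pseudocount 1 and 0.998 with each cell at 1000 UMIs, and that of the surfactant list -0.23 over members expressed in the class. Those of the transitional state and unfolded protein response lists were 0.015 and 0.092 with cells named one by one, and the latter was 0.31 under median-ratio scaling. The cell cycle median before the all-gene median was taken off went from 0.85 to 1.75 with pseudocount 1. It had no value with each cell at 1000 UMIs or over members expressed in the class.

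With each club-like cell at 1000 UMIs, Muc5b was found in 9.31% of control and 49.6% of Cre cells, Clca1 in 1.96% and 21.8% and Chil4 in 0.490% and 17.5%. Unthinned, these shares were 24.5% and 63.97%, 6.60% and 30.9%, and 1.89% and 36.03%. In thinned B cell-like cells, Muc5b was in 0.117% and 0.765%, Clca1 in 0% and 0.487% and Chil4 in 0% and 1.11%. Median depths of the club-like cells were 38338 and 23470 UMIs, and thinning left out 8 control and 20 Cre cells.

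**Figure D2:**
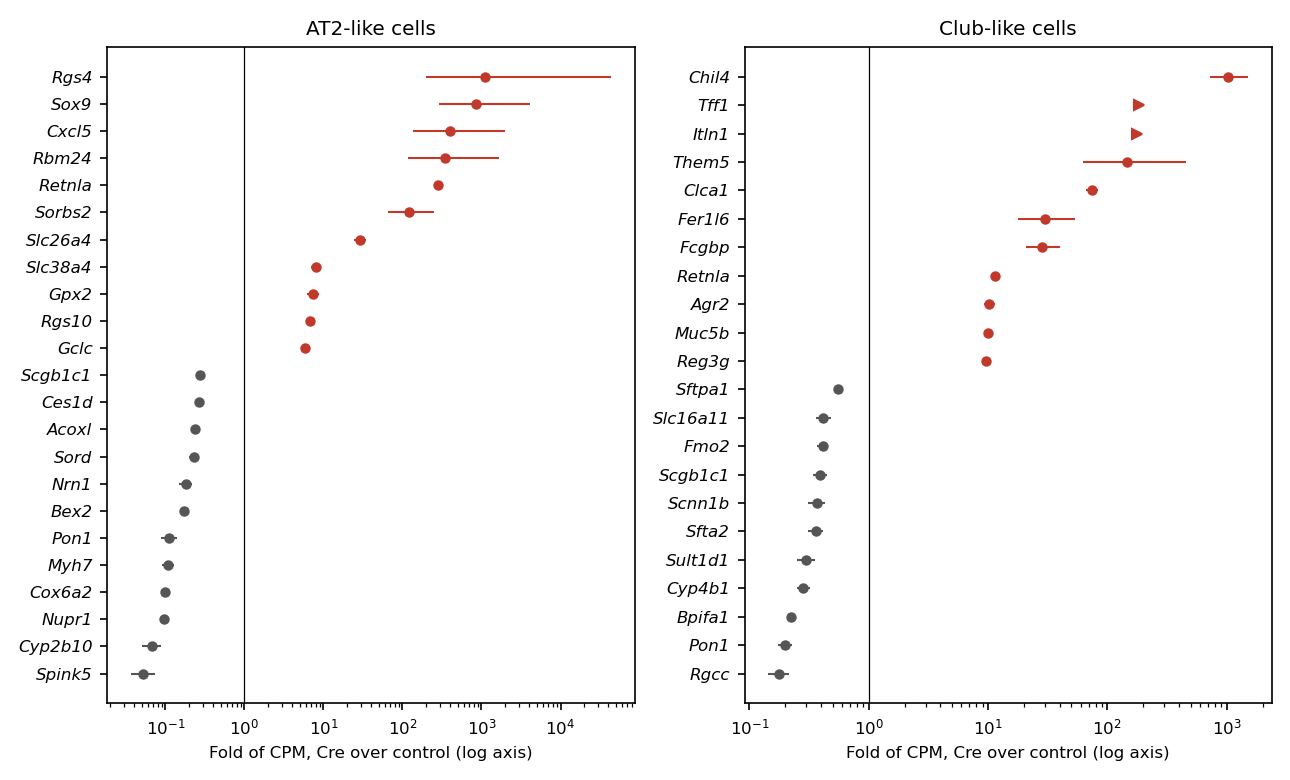
Fold of CPM, Cre over control (log axis), for genes among the 12 highest and 12 lowest by the fixed rule in AT2-like and club-like cells; points are folds, bars exact 95% intervals for counting error, and triangles lower bounds where the control held 0 UMIs. Sox9 and Retnla lie at 847-fold and 278-fold in AT2-like cells, and Clca1 at 74.7-fold in club-like cells.

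Ciliated-like cells, 94 control and 81 Cre cells, held fewer UMIs of immediate early genes in the Cre library. Ccno and Deup1, which act in the multiplication of centrioles, were 7.90-fold higher (4.22 to 16.4) and 5.002-fold higher (2.96 to 8.96), Agr2 was 25.7-fold higher (6.78 to 217) and Cox6b2, a respiratory chain subunit, 27.4-fold higher (9.08 to 135). Nos2, the inducible nitric oxide synthase, was 12.6-fold lower (6.39 to 28.3), Dclk1, a kinase of tuft cells, 12.3-fold lower (4.49 to 47.1), and Id1 and Id3, targets of BMP signalling, 3.32-fold lower (2.85 to 3.87) and 2.84-fold lower (2.39 to 3.39). Pmp22, Ccna1, Acot7, Cks2, Pcp4l1 and Dusp2 were between 4.16 and 9.53-fold higher, and Spp1, Efemp1, Gng13, Tspan15, Osgin1, Chia1 and Cdkn1c between 2.28 and 7.10-fold lower, though the signs of Pmp22, Spp1 and Gng13 turned when cells were named one by one, and that of Chia1 with the stricter filter. The cilia list had a relative median of -0.19, with 2 of 15 members higher and 1 lower, immediate early genes -0.94 (14 of 20 lower), fatty acid and sterol synthesis -0.41 and CRTC and CREB genes -0.02. With each cell at 1000 UMIs, the fatty acid and sterol median before the all-gene median was taken off went from -0.33 to -1.18. That of the CRTC and CREB list went from 0.066 to -0.60.

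Alveolar macrophage-like cells of the Cre library held more UMIs of many of the matrix and type 2 response genes measured. C4b, a complement component, was 146-fold higher (81.7 to 294), Fbp1, an enzyme of gluconeogenesis, 107-fold higher (49.2 to 293), Ccl17, a chemokine for type 2 helper T cells, 66.2-fold higher (33.4 to 154), Lrg1 22.4-fold higher (17.1 to 29.9) and Ch25h, cholesterol 25-hydroxylase, 11.3-fold higher (9.57 to 13.3). Chil3, a chitinase-like protein, was 2.52-fold higher (2.49 to 2.54) and Car4, a carbonic anhydrase, 3.70-fold higher (3.51 to 3.90). The keratin Krt79 was 11.6-fold lower (10.3 to 13.04), Acaa1b, a peroxisomal thiolase, 10.2-fold lower (9.23 to 11.2), Klf2, a transcription factor, 6.13-fold lower (5.69 to 6.61) and Fabp1, a fatty acid binding protein, 4.92-fold lower (4.61 to 5.24). Lpl, lipoprotein lipase, and Cidec, a lipid droplet protein, stood at 0.454 (0.442 to 0.466) and 0.225 (0.207 to 0.244) times the control level, while the fatty acid binding proteins Fabp4 and Fabp5 were 1.57-fold higher (1.505 to 1.64) and 2.49-fold higher (2.39 to 2.59). The alveolar macrophage identity list had a relative median of -0.08, with 4 of 18 members higher and 7 lower. Type 2 response (0.83, 9 of 13 higher and 0 lower), matrix (0.78, 9 of 17 higher and 0 lower), monocyte-derived macrophage (0.74, 11 of 16 higher and 1 lower) and protease genes (0.56) lay above the all-gene median of -0.07, and cell cycle (-0.53) and lipid handling genes (-0.32, 2 of 16 higher and 6 lower) below. The type 2 value was 0.36 with pseudocount 20 and 1.67 with each cell at 1000 UMIs. Of that list, Retnla, Chil4 and Il33 stood at 113, 7.39 and 3.64 CPM in the Cre library. B cell-like cells held 146, 10.96 and 4.50 CPM, so free RNA is not excluded as a part. B cell-like cells were shallower, at a median of 1988 against 9770 UMIs. Per cell, Retnla had 1.15 UMIs in alveolar macrophage-like, 0.341 in B cell-like and 0.812 in NK-like cells of the Cre library. Ccl17, Ccl24, Arg1 and Chil3 stood above the B cell-like level. Of the monocyte-derived list, C1qa stood at 7.18 against 7.03 CPM, and Spp1 at 873 against 35.7 CPM. The matrix value was 0.25 over genes with at least 1 UMI, 0.31 with pseudocount 20 and 0.32 with cells named one by one. The monocyte-derived value was 0.39 with pseudocount 20 and 1.30 over members expressed in the class. With each cell at 1000 UMIs, Ccl17 was found in 0 of 500 control cells, which allows a share of cells with a UMI of up to 0.6%, and in 4.25% of Cre cells, and Arg1, arginase 1, in 0.4% and 1.81%. Unthinned, these shares were 1.40% and 12.4% for Ccl17 and 0.6% and 8.70% for Arg1, at median depths of 9331 and 9770 UMIs. In thinned B cell-like cells Ccl17 was in 0.176% and 0.557% and Arg1 in 0% and 0.278%. Arg1 and Ccl24 stood at 39.02 and 58.3 CPM in alveolar macrophage-like cells of the Cre library and at 2607 and 4010.2 CPM in cluster 23. MHC class II genes lay at 0.999, but Cd74 and H2-Ab1 were under the level of the other cells, at 373 against 2230.5 CPM and 109 against 648 CPM in the Cre library.

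Interstitial macrophage-like cells held more UMIs of cell cycle genes and fewer of MHC class II genes in the Cre library. Spp1, or osteopontin, was 28.7-fold higher (20.99 to 40.4), Gpnmb, a membrane glycoprotein, 32.1-fold higher (12.3 to 119), Ccl17 63.7-fold higher (17.4 to 531) and Rnase2a, an eosinophil-type ribonuclease, 13.4-fold higher (8.94 to 20.9), and Arg1, with 0 control UMIs, was at least 50.6-fold higher than the floor. Mucl1 was 445-fold lower (79.3 to 17607), Lyz1, a lysozyme, 13.8-fold lower (9.70 to 20.2), Mmp9, a gelatinase, 3.14-fold lower (2.52 to 3.93), the metallothionein Mt1 2.995-fold lower (2.87 to 3.13) and Klf2 2.76-fold lower (2.56 to 2.97). Spp1, Arg1 and Rnase2a also lead cluster 23, which came from the Cre library alone. Spp1, Gpnmb and Arg1 stood at 19177, 730.03 and 2607 CPM there, against 723, 80.7 and 95.5 CPM in interstitial macrophage-like cells of that library. Over the other kept cells Spp1 was 37.1-fold and Rnase2a 146-fold higher in the Cre library. Cell cycle genes had a relative median of 0.87 (10 of 15 higher), MHC class II genes -0.76 and monocyte-derived macrophage genes 0.04, over an all-gene median of 0.16. The cell cycle value was 0.43 with each cell at 1000 UMIs, 0.57 with pseudocount 20 and 1.79 over genes with at least 100 UMIs, and median depths were 6767 and 3941 UMIs. With cells named one by one the MHC class II value was -1.26. In cDC2-like cells, cell cycle genes lay at 1.10 (11 of 15 higher), MHC class II genes at -0.67 (6 of 7 lower) and interferon response genes at -0.96, over an all-gene median of 0.22. The cell cycle value was 0.56 with pseudocount 20, and the MHC class II value -1.10 with cells named one by one. The eotaxin Ccl24, Il12b, a subunit of IL-12, and the apolipoprotein Apol7c had 0 control UMIs there and were at least 79.96-fold higher, at least 27.6-fold higher and at least 17.5-fold higher than the floor, and the fatty acid binding proteins Fabp4 and Fabp5 were 58.2-fold higher (15.9 to 484) and 16.02-fold higher (12.2 to 21.4). Ccl24, Fabp4 and Fabp5 stood at 272, 132 and 982 CPM in cDC2-like cells of the Cre library and at 4010.2, 1379 and 3374 CPM in cluster 23. Ccl2, a monocyte chemokine, was 6.69-fold lower (4.55 to 10.1), Cd209b 5.29-fold lower (3.57 to 7.99), the interferon-induced Ifitm3 4.54-fold lower (4.12 to 5.02), Ifitm6 3.83-fold lower (2.85 to 5.18) and Mt1 3.45-fold lower (3.20 to 3.71).

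Monocyte-like cells of the Cre library held fewer UMIs of neutrophil chemokine and NF-kB genes, and in neutrophil-like cells the list lay below the all-gene median. The list's relative median was -0.91 in classical monocyte-like cells (14 of 16 lower), -1.14 in nonclassical monocyte-like cells (11 of 14 lower) and -0.32 in neutrophil-like cells (7 of 16 lower). The neutrophil chemokine Cxcl2 was 4.03-fold lower (3.84 to 4.24) in classical and 4.68-fold lower (4.29 to 5.11) in nonclassical monocyte-like cells, where the cytokines Tnf and Il1b were 2.90-fold lower (2.63 to 3.20) and 2.76-fold lower (2.62 to 2.91), the chemokine Ccl4 3.01-fold lower (2.65 to 3.42) and the cystine transporter Slc7a11 3.87-fold lower (2.93 to 5.19). In classical monocyte-like cells Chil3 was 3.05-fold lower (2.86 to 3.25), Tnfsf9 3.57-fold lower (2.80 to 4.60), Marcksl1 2.63-fold lower (2.35 to 2.96) and the interferon-induced chemokine Cxcl10 2.49-fold lower (2.16 to 2.87), while Rgs2, Dusp6, Rhob, Tsc22d3 and Fam46a were between 2.30 and 2.76-fold higher. CRTC and CREB genes lay at -0.96 in nonclassical monocyte-like cells, over an all-gene median of 0.15, but at -0.31 when genes with as few as 1 UMI were counted. In neutrophil-like cells Osm, or oncostatin M, was 2.64-fold higher (2.42 to 2.87) and Arl4c 4.08-fold higher (3.105 to 5.38), and Wfdc17, Stfa2, Prok2, Hilpda and Ly6g were between 2.41 and 4.28-fold lower. All-gene medians were 0.17 in classical monocyte-like and 0.30 in neutrophil-like cells.

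ILC2-like cells of the Cre library held more UMIs of the type 2 cytokine gene Il13 and of cell cycle genes. Il13, a cytokine that drives mucous metaplasia, was 7.46-fold higher (5.49 to 10.4), Ptgs2, cyclooxygenase 2, 5.47-fold higher (4.29 to 7.08), Il1r2, a decoy receptor for IL-1, 42.8-fold higher (7.50 to 1705.5), Ctla4, an inhibitory receptor, 12.6-fold higher (4.16 to 62.1) and Mki67, a proliferation marker, 8.82-fold higher (3.94 to 24.5). Cd3g, a chain of the T cell receptor complex, was 6.97-fold lower (4.19 to 12.04), Gimap3 3.13-fold lower (2.35 to 4.19) and Ubb, Dad1 and Hcst between 1.91 and 2.22-fold lower. The type 2 response list had a relative median of 0.75, with 5 of 9 members higher and 0 lower, and the cell cycle list one of 0.85 (11 of 15 higher), over an all-gene median of 0.23; with each cell at 1000 UMIs the cell cycle value was 0.12, and with cells named one by one 0.25. The type 2 value was 0.36 over genes with at least 1 UMI and 1.21 with cells named one by one. With each cell at 1000 UMIs, Il13 was found in 5.04% of control and 19.3% of Cre ILC2-like cells and Il5 in 17.99% and 20.8%. Unthinned, Il13 was in 12.8% and 31.99% and Il5 in 41.1% and 36.97%. The log2 fold of Il5 was 0.30, close to the all-gene median, and it turned to -0.095 with cells named one by one. The type 2 list also holds Retnla, whose source in lymphoid classes was not settled. Thinned B cell-like cells had Il13 in 0 of 1704 control and 0 of 1437 Cre cells, which allows shares of cells with a UMI of up to 0.176% and 0.209%. Median depths of ILC2-like cells were 4503 and 3554 UMIs, and thinning left out 2 control and 8 Cre cells.

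In Treg-like cells of the Cre library the chemokine Ccl1 was 41.8-fold higher (11.3 to 350.2), Calca, the precursor of calcitonin gene-related peptide, 7.25-fold higher (4.37 to 12.8), Il10, an anti-inflammatory cytokine, 5.69-fold higher (3.29 to 10.6), Il1rl1, the receptor for IL-33, 3.53-fold higher (2.92 to 4.29) and Sorl1 3.94-fold higher (2.91 to 5.41). Ccl1, Il1rl1 and Calca also lead the ILC2-like cluster, and the ILC2 cytokines Il5 and Il13 were 7.17-fold higher (3.26 to 18.6) and 5.09-fold higher (2.48 to 11.7) in Treg-like cells. The sign of Il5 turned there when cells were named one by one, and that of Il13 with each cell at 1000 UMIs. Cell cycle genes had a relative median of -0.75 (9 of 16 lower) and interferon response genes -0.82 (7 of 11 lower), over an all-gene median of 0.17. With cells named one by one these were -0.48 and -0.54, and the log2 ratio of Mki67 turned from -0.31 to 0.13. The interferon value was -0.41 with each cell at 1000 UMIs and -0.46 over genes with at least 1 UMI, and median depths were 5192 and 3186 UMIs. Ifi27l2a, an interferon-induced gene, was 2.95-fold lower (2.77 to 3.15), Cd7 3.70-fold lower (2.72 to 5.12), Tyms, thymidylate synthase, 3.16-fold lower (2.14 to 4.76) and Crip1 2.42-fold lower (2.32 to 2.53). T cell-like cells held more UMIs of Rag1 (17.3-fold, 14.2 to 21.3) and Dntt (26.1-fold, 19.1 to 36.7), which act in the rearrangement of antigen receptor genes, and of Arpp21, Endou and Aqp11, from 16.97 to 25.2-fold higher. The cytotoxic genes Gzma and Gzmb were 4.56-fold lower (4.27 to 4.87) and 4.18-fold lower (3.61 to 4.86), the chemokines Ccl5 and Ccl4 3.84-fold lower (3.73 to 3.95) and 2.71-fold lower (2.27 to 3.27), and the NK receptor Klre1 3.45-fold lower (2.72 to 4.42). The class joined 3 clusters, of which cluster 29, led by Rag1 and Dntt, held 16 control and 224 Cre cells, and cluster 25, led by Ccl5 and Gzmb, held 224 control and 114 Cre cells. Without cluster 29 the log2 fold went from 4.71 to 2.20 for Dntt, which then rested on 2 control and 5 Cre UMIs, all in cluster 6. For Rag1 it went from 4.12 to 3.104, a value against the floor of 3 counts. Clusters 6 and 25 held 0 control UMIs of Rag1, and 13 and 1 Cre UMIs. It went from 4.66 to 1.30 for Arpp21, from -2.19 to -2.02 for Gzma and from -2.06 to -1.81 for Gzmb. Within cluster 25 Gzma stood at 5898 CPM in the control and 2086 CPM in the Cre library. Immediate early genes lay at 0.42 and CRTC and CREB genes at -0.25, over an all-gene median of 0.24.

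Alveolar fibroblast-like cells of the Cre library held more UMIs of chemokine genes and fewer of fibroblast identity genes. Ccl11, the eosinophil chemokine eotaxin, was 27.2-fold higher (16.2 to 50.002), the monocyte chemokines Ccl2 and Ccl7 18.8-fold higher (12.98 to 28.5) and 26.2-fold higher (12.6 to 65.4), Cxcl10 10.9-fold higher (8.45 to 14.4) and Ptgs2 18.8-fold higher (12.9 to 28.3). With each cell at 1000 UMIs, Ccl11 was found in 0.673% of control and 6.72% of Cre cells and Ccl2 in 1.12% and 7.15%; unthinned, the shares were 1.23% and 9.13%, and 1.12% and 9.47%. Thinned B cell-like cells had Ccl11 in 0% and 0.278% and Ccl2 in 0.117% and 0.557%, and thinning left out 448 control and 509 Cre alveolar fibroblast-like cells. Gsta3, a glutathione transferase, was 5.46-fold lower (4.71 to 6.33), Ccdc42 6.94-fold lower (4.87 to 10.1), Colq 5.49-fold lower (4.35 to 6.97), the matricellular protein gene Wisp2 4.09-fold lower (3.45 to 4.86) and Faim2 3.74-fold lower (2.88 to 4.87). The chemokine and NF-kB list had a relative median of 0.87 (9 of 14 higher), the unfolded protein response 0.70, CRTC and CREB genes 0.46 and matrix genes 0.43. The chemokine value was 0.56 over genes with at least 1 UMI and 1.62 over members expressed in the class. Fibroblast identity genes lay at -0.62 (9 of 16 lower); Wnt2, a ligand of the Wnt pathway, stood at 0.370 (0.304 to 0.450) times the control level, Gpx3, a secreted glutathione peroxidase, at 0.376 (0.361 to 0.392) and Inmt, a methyltransferase, at 0.487 (0.475 to 0.498). The class joined clusters 8 and 9, and the deeper, cluster 8, held 359 of the control and 832 of the Cre cells.

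In adventitial fibroblast-like cells Calca, with 0 control UMIs, was at least 88.5-fold higher than the floor, Col6a5, a collagen chain, 68.6-fold higher (18.7 to 571), Lif, a cytokine of the IL-6 family, 4.78-fold higher (3.48 to 6.72), Thbs1, thrombospondin 1, 2.78-fold higher (2.63 to 2.95) and Ccl11 2.83-fold higher (2.52 to 3.19). Lrat, which esterifies retinol, was 3.83-fold lower (2.76 to 5.39), Gsta3 3.18-fold lower (2.30 to 4.46), the cold-induced RNA-binding protein Cirbp 2.59-fold lower (1.96 to 3.44), and Igfbp6 and Klf2 2.02-fold lower (1.93 to 2.12) and 2.02-fold lower (1.90 to 2.14). Chemokine and NF-kB genes lay at 0.61, matrix genes at 0.27 and fibroblast identity genes at -0.23, over an all-gene median of 0.11. The chemokine value was 0.12 with cells named one by one, 0.25 over members expressed in the class and 0.33 with each cell at 1000 UMIs. Before the all-gene median was taken off, the fibroblast identity median turned from -0.12 to 0.040 with cells named one by one. In smooth muscle-like cells matrix genes lay at 0.52 (9 of 20 higher), over an all-gene median of 0.18; Tnc and Fn1, tenascin C and fibronectin, were 11.7-fold higher (7.15 to 20.4) and 11.8-fold higher (8.996 to 15.7). Ccl11 was 96.9-fold higher (26.5 to 805), Cck, or cholecystokinin, 83.2-fold higher (14.6 to 3315), Ccl7 28.2-fold higher (14.7 to 62.3), Spp1 23.01-fold higher (14.4 to 39.1), against 37.02-fold over the other kept cells, and Il1rl1, with 0 control UMIs, at least 18.8-fold higher than the floor. Igfbp3, Tnfaip6, Pnmt, Has1 and Mt1 were between 3.68 and 7.27-fold lower there, though Has1 turned sign when cells were named one by one. With each cell at 1000 UMIs the log2 value of Il1rl1 was -0.87. Its control side of 0 UMIs was set at the floor of 3 counts, so this is no reversal.

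General capillary-like endothelial cells of the Cre library held fewer UMIs of interferon-induced and immediate early genes. Interferon response genes lay at -0.70 (8 of 13 lower), and Irgm1 and Iigp1, GTPases induced by interferon, were 3.75-fold lower (2.71 to 5.30) and 2.78-fold lower (2.38 to 3.27). Resp18 was 62.7-fold lower (10.9 to 2513), the immediate early gene Egr3 6.31-fold lower (3.83 to 10.999) and Tmem252 3.73-fold lower (3.04 to 4.59). Cell cycle genes lay at 0.91, with Top2a, a topoisomerase of dividing cells, 6.13-fold higher (3.44 to 11.7); the list's value was -0.016 over genes with at least 100 UMIs, 0.21 with the stricter filter and 0.49 with cells named one by one. The neutrophil granule gene Ngp was 27.5-fold higher (9.06 to 136), the matrix genes Mfap4 and Npnt 5.34-fold higher (4.29 to 6.68) and 5.80-fold higher (4.19 to 8.20) and Nts, or neurotensin, 7.82-fold higher (3.87 to 17.9), a sign that turned without doublet removal. Fibroblast identity genes lay at 1.33, but at 0.44 when cells were named one by one and 0.72 over genes with at least 100 UMIs, immediate early genes at -0.56 and capillary endothelium genes at -0.03. General capillary-like cells were shallow, with median depths of 815 and 904 UMIs. Alveolar fibroblast-like cells held 2095410 control and 5424048 Cre UMIs, so free RNA is not excluded as a source of the fibroblast genes. In aerocyte-like cells capillary endothelium genes lay at -0.03 and immediate early genes at -0.86; Apold1, an endothelial early response gene, was 5.70-fold lower (2.44 to 16.3), Cebpd 3.16-fold lower (2.42 to 4.17) and Sbno2, Ech1 and Tspan17 between 3.08 and 4.36-fold lower. The platelet chemokine Pf4 was 16.8-fold higher (6.14 to 64.3) there, a sign that turned when cells were named one by one, and Stip1, a cochaperone, was 4.22-fold higher (2.43 to 7.67). In venous-like cells immediate early genes lay at -0.78, Ccl4 was 11.1-fold lower (6.43 to 20.8) and Igfbp5 2.74-fold higher (2.43 to 3.09). Acta2, or smooth muscle actin, was 9.45-fold higher (4.91 to 20.4) there, and Rbp7 and Olfm2 were 9.92-fold lower (5.603 to 19.1) and 7.79-fold lower (4.26 to 15.6), signs that turned when cells were named one by one.

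**Figure D3:**
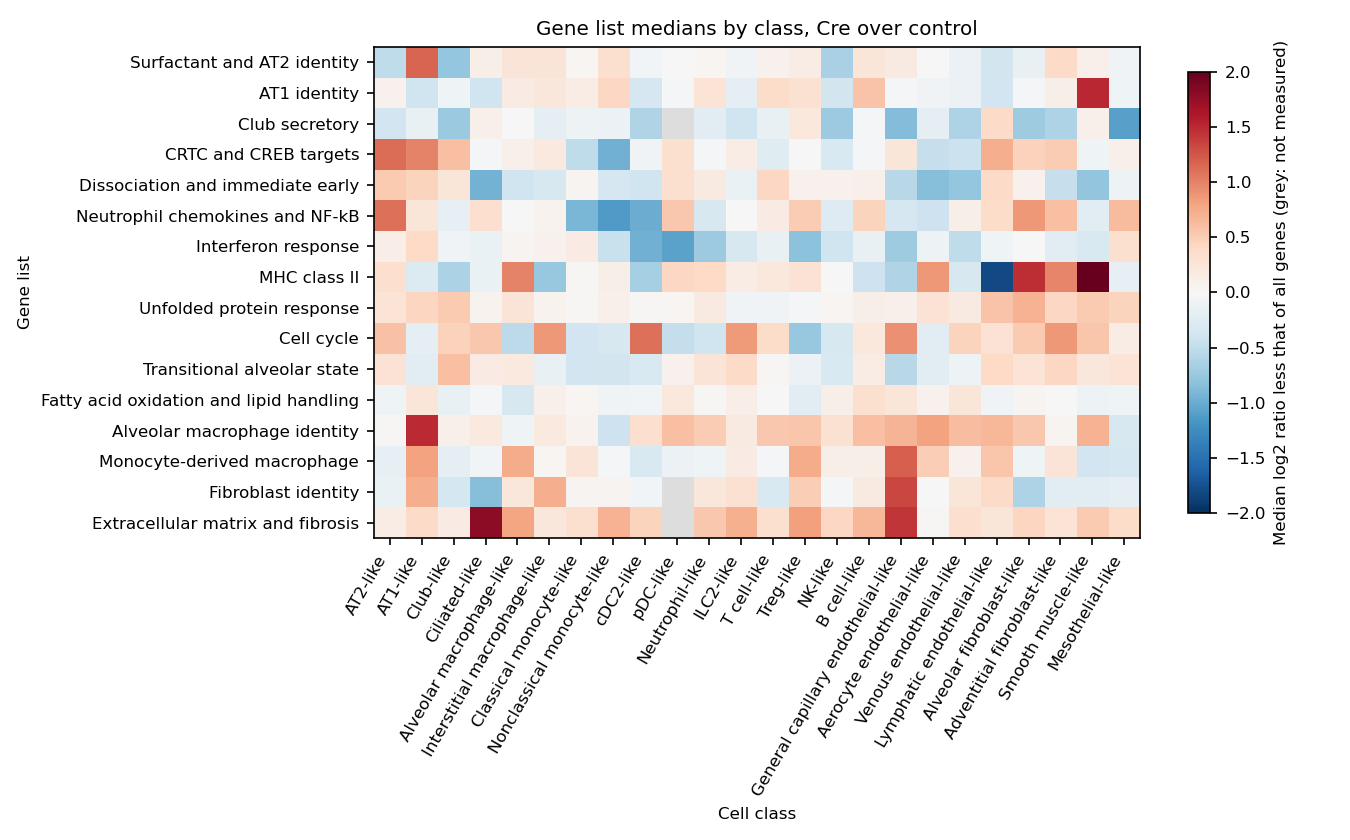
Relative median log2 ratio, Cre over control, of 16 gene lists in 24 cell classes (color scale; grey, not measured). Each cell of the map is the median of the list's measured genes less that of all measured genes of the class; the CRTC and CREB list reaches 1.12 in AT2-like cells and the surfactant and AT2 identity list -0.77 in club-like cells.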

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

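All tests of explanations in this part, on Rag1 and Dntt, on Retnla and on the CRTC and CREB list, were chosen after the result was seen. Of the barcodes of the Cre library, 6.15% had under 200 genes and were left out of every comparison, and 91.7% of their UMIs were haemoglobin, a signal in data the comparisons do not use; in the control library such barcodes were 0.633%, with 93.3% haemoglobin.

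Lists with at least 10 measured members that lay at least 1.5-fold above the all-gene median in one class and as far below it in another, beyond 99% of random lists on each side, stand out, though the differences between classes were not tested. The CRTC and CREB list lay at 1.12 in AT2-like and -0.96 in nonclassical monocyte-like cells, and the neutrophil chemokine and NF-kB list at 1.10 and -1.14 in the same classes. Cell cycle genes lay at 1.10 in cDC2-like and -0.75 in Treg-like cells. Fibroblast identity genes lay at 1.33 in general capillary-like cells, where free RNA is not excluded, and at -0.62 in alveolar fibroblast-like cells. Surfactant and AT2 identity genes lay at 1.16 in AT1-like and -0.77 in club-like cells. Several of these values were over 1.5 times smaller in an alternative. With cells named one by one, the fibroblast list in general capillary-like cells was 0.44, the chemokine list in AT2-like cells 0.66, the cell cycle list in Treg-like cells -0.48 and the surfactant list in club-like cells -0.24. Over genes with at least 1 UMI, the fibroblast list in general capillary-like cells was 0.76 and the CRTC and CREB list in nonclassical monocyte-like cells -0.31. With a pseudocount of 20 CPM, the cell cycle list in cDC2-like cells was 0.56, and with each cell at 1000 UMIs the surfactant list in AT1-like cells was 0.34.

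The CRTC and CREB list in AT2-like cells was set against dissociation and depth, with the gene on both lists left out of the test on dissociation. Over 20 classes outside the epithelium, with erythroid-like cells left out, a line related its median to that of the dissociation list. Its slope was 0.24 over dissociation medians from -0.77 to 0.73, against a residual SD of 0.39. The lists were thus related too weakly for this line to decide on dissociation. AT2-like cells lay 2.45 residual SDs above it, past a limit of 2. That limit was itself set after the value was seen, and the spread is over classes of the same 2 libraries, which are not independent replicates. Club-like cells lay 1.92, lymphatic-like cells 1.78, adventitial fibroblast-like cells 1.70 and AT1-like cells 1.68 above. With each cell at 1000 UMIs the relative median was 0.94 (0.74 to 1.25). The value thus did not rest on the greater weight of deeper cells in the sum. Thinning keeps each cell's gene proportions on average, so it cannot decide on other differences that come with depth. LKB1 restrains CRTC coactivators through the SIK kinases, so a higher level of their targets, 1.12 here, may follow the genotype. With 1 library per genotype that cannot be told apart from another difference between the pools.

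Retnla had more UMIs in the Cre library in nearly every class. In AT2-like cells of that library the mean was 161 (90.3 to 346) times that of the highest of the B, T, NK and neutrophil-like classes, which excludes evenly spread free RNA as the source there. Among those lymphoid and neutrophil-like classes the highest mean was 2.42 (1.13 to 4.35) times the lowest, against a limit of 2, so free RNA may account for their UMIs and is not settled; the interval, over resampled cells, was added after the point value, which alone lay past the limit, had been seen. The genotype may account for the 278-fold (258 to 299.5) level in AT2-like cells, which 1 library per genotype cannot decide.

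The T cell-like cluster led by Rag1 and Dntt came mostly from the Cre library. Its median depth was 0.488 (0.462 to 0.526) times that of the largest T cell-like cluster, while doublets would be deeper, which argues against doublets. Against that cluster, Cd4 was 4.34-fold higher (3.52 to 5.35). Ptcra and Rag2 were 68.7-fold (10.8 to 2872) and 206-fold higher (35.4 to 8301), each against 1 UMI in the largest cluster. These values go with immature T cells of thymic type in the suspension, from within the lung or from thymic tissue taken with it. The log2 ratio of its shares was 3.56 (2.83 to 4.40), and whether the genotype or the dissection of 1 pool set it cannot be told apart.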

How the results depend on the processing

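No paired analysis was possible because each genotype has 1 library and the groups share fewer than 2 replicate numbers. Chosen after the result was seen were the denominator without erythroid-like cells, the T cell-like class without the cluster led by Rag1 and Dntt, the deeper alveolar fibroblast-like cluster alone and the members expressed in the class; the other alternatives were planned. Values are log2, and list medians are given here before the all-gene median is taken off. Of 255 alternative values of 27 shares, 219 lay within the counting interval of the reported value, 28 moved beyond it and 8 turned sign. Of 753 for 84 list medians these counts were 518, 227 and 8, and of 2344 for 388 genes, some of them list members not printed elsewhere, 1618, 701 and 25. A turn of sign was counted where the reported interval excluded 0. There was no value for 38 combinations, such as ciliated, classical monocyte, venous, Treg, plasma cell and pDC-like shares with Leiden resolution 0.5, which formed no cluster of that name, folds with 0 control UMIs as a mean over cells, and lists left with too few members. Classes with few or shallow cells limit what can be seen: AT1-like cells had median depths of 978.5 and 1022 UMIs, near the 1000 UMIs to which cells were thinned. Those of general capillary-like cells were 815 and 904 UMIs, and those of aerocyte-like cells 878 and 1087 UMIs.

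For shares, naming each cell from its own markers gave -0.050 for AT2, -0.43 for club, 1.64 for ILC2 and 0.084 for venous-like cells. Within the lineage, AT2 had -0.061, aerocyte -0.31, general capillary -0.080, neutrophil -0.94 and venous-like cells 0.30. With the libraries clustered separately, adventitial fibroblast had -0.12, aerocyte -1.23, ciliated -0.96, plasma cell -0.25, venous 0.73 and cDC2-like cells 0.63. The stricter filter gave -0.69 for aerocyte-like cells and Leiden resolution 0.5 gave -0.094 for alveolar fibroblast-like cells. The signs that turned were those of AT2, adventitial and alveolar fibroblast, plasma cell and venous-like cells. Reported intervals that included 0 were not counted as turns, such as those of club-like cells, of lymphatic-like cells, with 0.39 within the lineage, and of T cell-like cells, with 0.16 under separate clustering. The cause was not tested, except that a denominator within a lineage removes the other lineages. Per-cell naming also has goblet markers as a class of their own, so the cells highest in them leave the club-like class.

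For genes that turned, thinning gave -1.45 for Etv5 and -0.45 for Trp53inp1 in AT1, 0.16 for Chia1 in ciliated, -0.30 for Top2a in club, -0.87 for Il1rl1 in smooth muscle and -0.21 for Il13 in Treg-like cells. A library with 0 UMIs was set at the floor of 3 counts, so the value of Il1rl1, with 0 control UMIs, is no reversal. Turns of genes with few UMIs, such as Etv5 and Trp53inp1, may also come from that floor. The mean over cells gave -0.34 for Slc34a2 in AT1, the stricter filter 0.42 for Chia1 in ciliated, and no doublet removal -0.24 for Nts in general capillary-like cells. Per-cell naming gave -0.15 for Pf4 in aerocyte-like cells; 1.40 for Gng13, -0.066 for Pmp22 and 3.25 for Spp1 in ciliated-like cells; -0.89 for Fcgbp, -0.47 for Foxa3, -2.21 for Reg3g, -1.38 for Scgb3a1 and -2.07 for Tff2 in club-like cells; and -0.095 for Il5 in ILC2-like cells. It also gave 4.50 for Has1 in smooth muscle, -1.62 for Il5 and 0.13 for Mki67 in Treg, and -1.52 for Acta2, 1.29 for Olfm2 and 0.44 for Rbp7 in venous-like cells. Foxa3 and Tff2 are goblet markers, and per-cell naming takes the cells highest in those markers out of the club-like class. It therefore cannot test these 2 genes there. The cause of the other turns was not tested.

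In AT2-like cells the surfactant median of -0.35 was -0.60 with median-ratio scaling, -0.33 thinned and -0.28 with per-cell naming. The CRTC and CREB median of 1.28 was 1.40 and 0.99 with pseudocounts 1 and 20, 1.10 with median-ratio scaling and 1.15 thinned. The chemokine and NF-kB median of 1.26 was 1.32 and 0.71 with pseudocounts 1 and 20, 1.39 from 100 UMIs, 1.06 with median-ratio scaling, 1.36 thinned, 0.80 with per-cell naming and 1.43 over expressed members. In club-like cells the goblet median of 2.36 was 2.80 and 1.34 with pseudocounts 1 and 20, 2.81 from 100 UMIs, 2.03 with median-ratio scaling, 3.44 thinned and 0.19 with per-cell naming, and the club secretory median of -0.36 was -0.99, -0.53 and -0.40 with median-ratio scaling, thinned and per-cell naming. The type 2 median of 0.98 in ILC2-like cells was 0.53 from 1 UMI, 1.44 with per-cell naming and 0.63 over expressed members. Fibroblast identity in alveolar fibroblast-like cells, at -0.58, was -0.72 thinned and -0.37 with per-cell naming. Alveolar macrophage identity, at -0.15, was -0.052 with median-ratio scaling and -0.059 thinned, and cilia genes in ciliated-like cells, at -0.11, were 0.11 with per-cell naming. Medians that turned were NRF2 and oxidative stress in AT2 (-0.053), dissociation (-0.0066) and cilia (-0.24) in club-like cells with median-ratio scaling; fibroblast identity in adventitial (0.040), surfactant in club (0.076) and monocyte-derived genes in interstitial macrophage-like cells (-0.32) with per-cell naming; surfactant in club over expressed members (0.16); and interferon genes in classical monocyte-like cells from 100 UMIs (-0.078). The cause was not tested.

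Taken less the all-gene median of the same setting, 39 of these list medians lay 1.5-fold or more from that median. In at least 1 alternative 3 of them turned, 23 shrank by over 1.5 times and 10 grew by as much, while 13 did none of these. Those that turned were goblet genes in club-like cells (-0.13, per-cell naming), type 2 genes in club-like cells (-0.0014, from 1 UMI) and cell cycle genes in general capillary-like cells (-0.016, from 100 UMIs). The goblet value cannot be tested by per-cell naming, which takes the cells highest in goblet markers out of the club-like class. In alveolar macrophage-like cells the type 2 list went from 0.83 to 0.36 with pseudocount 20 and 1.67 thinned, the matrix list from 0.78 to 0.25 from 1 UMI, and the monocyte-derived list from 0.74 to 0.39 with pseudocount 20 and 1.30 over expressed members. Cell cycle genes went from 0.85 to 0.12 thinned in ILC2-like cells, and from 0.87 to 0.43 thinned and 1.79 from 100 UMIs in interstitial macrophage-like cells. The chemokine list went from 0.87 to 1.62 over expressed members in alveolar and from 0.61 to 0.12 with per-cell naming in adventitial fibroblast-like cells, and interferon genes in Treg-like cells from -0.82 to -0.41 thinned. The cause of the other changes was not tested.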

Other observations

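No test of an explanation is reported in this part, and the gene shared between classes was picked out after its values were seen. Interferon response genes lay below the all-gene median in several immune and endothelial classes of the Cre library. The relative median was -0.72 in neutrophil-like cells (9 of 16 lower), -1.07 in plasmacytoid dendritic-like cells (5 of 5 lower), -0.45 in nonclassical monocyte-like cells (6 of 14 lower) and -0.51 in venous-like cells (6 of 13 lower). In classical monocyte-like cells it was 0.16, with 4 of 18 members higher and 2 lower. Ifi27l2a, an interferon-induced gene, was 1.94-fold lower (1.83 to 2.05) in B cell-like cells.

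Hsph1, a heat-shock protein of the HSP110 family, was among the 5 highest genes in each of 5 classes in the Cre library. It was 11.2-fold higher (4.77 to 32.1) in aerocyte-like, 4.26-fold higher (2.74 to 6.80) in nonclassical monocyte-like, 3.80-fold higher (2.98 to 4.87) in B cell-like, 3.78-fold higher (2.49 to 5.91) in venous-like and 3.39-fold higher (2.38 to 4.95) in NK-like cells. Over the remaining kept cells beside each of these classes Hsph1 was between 4.04 and 4.10-fold higher in the Cre library, so the difference was not particular to these classes, and of the 5 intervals only that of aerocyte-like cells lay above those values. Haemoglobin genes made up 0.689% of the UMIs of kept control cells and 1.86% of those of kept Cre cells.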
